A study of Arabidopsis thaliana with 4 samples.

How the data were processed

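RNA sequencing values of Arabidopsis thaliana Col-0 roots were used from 4 libraries. Seedlings had grown for 8 days at 625 µM phosphate (plus_Pi, 2 libraries) or at 5 µM phosphate (low_Pi, 2 libraries), per the labels. The name of the deposited table also calls the roots dark grown, which the sample labels leave unsaid. Per the labels' protocols, total RNA was treated with DNase I, polyadenylated RNA was selected with oligo(dT) beads, and fragmented RNA was made into Illumina libraries. The protocols do not mention strand. The submitters' processing notes list CASAVA 1.4, FastQC, HISAT2, HTSeq and edgeR, without the role of each. The genome build and annotation were not given in the sources used here, and no coordinates are printed.

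The authors deposited 1 table of 27655 genes by 4 columns of whole numbers, called normalized counts, with the normalization not given in the sources used here. Because the deposited values are called normalized, they were treated as a score without a known read depth, and no count model was fitted to them. Columns were matched to samples by name. The second low_Pi column was matched by its name to its group only, because that name without punctuation also spells the title of a plus_Pi library. Its replicate number is the one in the column name. Its values lay with low_Pi replicate 1: the gene IPS1 had 26144 and 27943 in these columns, against 99 and 412 in the plus_Pi columns. Column totals were 42069421 and 38831704 for low_Pi replicates 1 and 2, and 40584090 and 44635953 for plus_Pi replicates 1 and 2. No counting interval was computed from them. Gene names came from the TAIR10.1 RefSeq gene table, which held 27445 of the 27655 identifiers. The other 210 are chloroplast-encoded and mitochondria-encoded identifiers.

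The 2 columns of a group were compared first. With a common ratio fitted per pair, the chi-square per gene was 0.278 for low_Pi over 18202 genes and 0.437 for plus_Pi over 18472 genes, where independent read counts give about 1. Between low_Pi replicate 1 and plus_Pi replicate 1 it was 258. The pairs thus differed by less than sampling noise would give if the values were read counts. Because the deposited values may have been scaled down, this does not settle whether the libraries are independent, and the mean of the 2 columns was used with each group counted as 1 sample as the cautious choice. No difference between the groups therefore has a replicate check, and no p-value, standard deviation or standard error is given for any gene. Nothing in the labels says that same-group libraries came from separate cultures.

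Values were used as deposited. A pseudocount of 41.5 (a fixed share of the mean column total) was added before taking log2, and log2 differences are low_Pi minus plus_Pi, averaged over columns. This scale understates differences of genes with low values. Genes entered with a mean of at least 41.5, which left 18729. The median log2 difference of these genes was -0.26. Genes were called higher or lower at a 2-fold difference, a size rule that replaced the planned significance threshold. The planned test was limma 3.58.1 in R 4.3.3, with a variance trend and Benjamini-Hochberg adjustment, followed by camera with a preset inter-gene correlation of 0.01. It was run over the 4 columns, but its p-values measure only the spread between columns of a group, and its counts appear with the processing alternatives alone.

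Before the data were examined, 31 gene lists with 471 entries were fixed by identifier, and 8 families by product description or identifier prefix. Families matched by description are broad: the ribosomal family takes in organellar proteins and the histone family takes in histone methyltransferases. The position of a list is the percentile of its median log2 difference among the medians of 10000 random lists with the same number of genes in each of 20 bins of mean value, which describes these libraries only. Named genes followed a rule fixed at the same time. It took the 10 largest differences in each direction with a mean of at least 415 and no overlap between the groups' columns, and up to 3 members per list at least 2-fold apart, or the 2 members with the highest mean where there were none. IPT2, IPT9, CYP735A1, CYP735A2, IPS1, SPX1, PHT1;4 and MGD3 were always included. Other members of the lists are named as examples chosen after their values were seen.

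Alternatives covered the pseudocount, the filter, median-of-ratios scaling, trimmed-mean scaling, quantile normalization, the replicate block and the omission of each library. Alternatives chosen after seeing the data were fold sizes of 1.5 and 4, a common column total, linear group means, the positions of lists among genes with a mean of at least 208, the choice of genes by their ratio to plus_Pi replicate 2 and subtraction of a fitted low_Pi share from plus_Pi replicate 2. That share came from weighted least squares over 18491 genes, with a percentile interval from 1000 resamples of genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The procedures were tested on simulated data. For the simulated low_Pi against plus_Pi comparison over 18707 genes, limma called 98 of 99 genes changed 2-fold and 95 of 95 changed 4-fold. Those simulated columns were independent, varied by more than sampling noise and were scaled to a common total. The result therefore does not measure how limma performs on the deposited columns. A simulated share of 1% gave 0.985% over 18491 genes, and 2 of 100 random lists lay in the outer 5% of percentiles. The simulated share was mixed from the same columns that the fit used. Its recovery therefore does not show that the deposited column is a mixture.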

Results

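The transcriptomes of roots grown for 8 days with 625 µM phosphate (plus_Pi) or 5 µM phosphate (low_Pi) were compared, in a study on the role of cis-zeatin, a cytokinin, in root responses to phosphate starvation. Each group had 2 libraries, with column totals between 38831704 and 44635953. The columns of a group differed by less than sampling noise would give if the values were read counts, and were counted as 1 sample because their independence is open, so the differences below have no replicate check. Of 18729 genes, 857 were at least 2-fold higher and 838 at least 2-fold lower in low_Pi. With median-of-ratios scaling the split was 1235 higher and 428 lower, with trimmed-mean scaling 1215 and 440, and with quantile normalization 1103 and 500. The median gene lay at a log2 difference of -0.26.

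The 10 largest gains included members of all 4 phosphate lists, while AT5G20790, AT3G25240, AT2G45135 and OCT1 were on none. PEPC1 (AT1G17710), a phosphatase-related gene, averaged 43599 in low_Pi and 421 in plus_Pi (log2 6.83). IPS1 (AT3G09922), a non-coding RNA that sequesters miR399, averaged 27044 and 256 (log2 6.74). SPX3 (AT2G45130), a phosphate-sensing SPX-domain gene, stood at log2 6.46, and MGD3 (AT2G11810), a galactolipid synthase, at 6.20. PPsPase1 (AT1G73010), a pyrophosphatase, was at 6.09, OCT1 (AT1G73220) at 5.75 and the phosphate transporter gene PHT1;2 (AT5G43370) at 5.75. PHT1;2 is uncertain because reads of near-identical PHT1 copies could be split between them. AT5G20790 (log2 6.36), AT3G25240 (6.25) and AT2G45135 (5.82) completed the 10 largest gains. Differences of at least 16-fold were found for 40 genes higher and 11 genes lower in low_Pi.

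The size of the strongest gains depended on the plus_Pi library. IPS1 had 99 in plus_Pi replicate 1 and 412 in replicate 2, which gave log2 differences of 7.59 and 5.90. PEPC1 gave 7.74 and 5.92, SPX3 7.10 and 5.81, MGD3 6.85 and 5.55, and AT5G20790 6.99 and 5.73 against replicates 1 and 2. PPsPase1 had 411 and 986 in these columns, which moved its difference by over 1.5-fold either way. SPX1 (AT5G20150) averaged log2 5.61, with 6.07 and 5.16 against the same columns, while PHT1;4 (AT2G38940) averaged 3.82. With a pseudocount of 208, AT5G20790 was at 5.68, SPX3 at 5.49, MGD3 at 5.44 and AT3G25240 at 4.76, and IPS1 and AT2G45135 were also over 1.5-fold less apart.

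**Figure D1:**
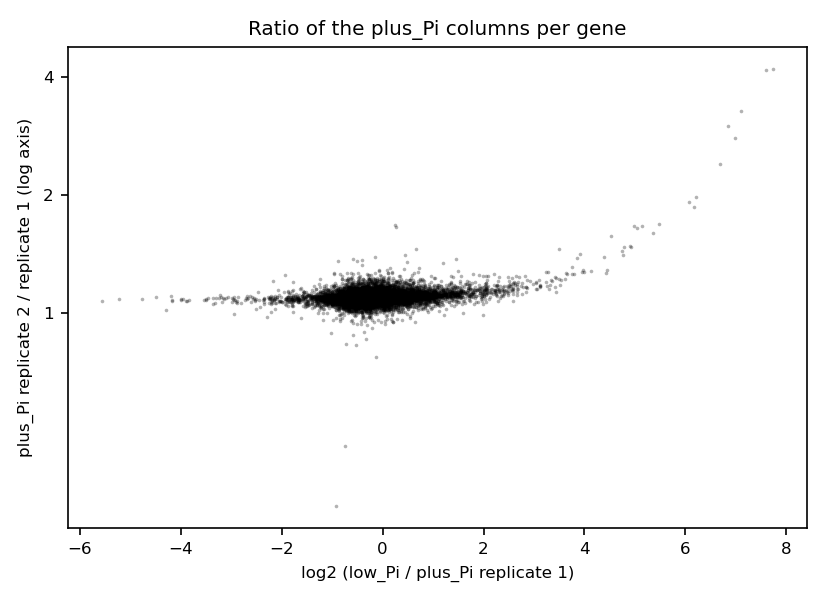
Ratio of plus_Pi replicate 2 to replicate 1 (vertical, log axis) against the log2 ratio of low_Pi to plus_Pi replicate 1 (horizontal), with 1 point per gene whose plus_Pi mean was at least 100. The ratio lies near 1.1 for most genes and climbs above 4 for IPS1 and PEPC1.

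Phosphate transport, phosphatases and lipid remodelling were higher as groups. Of 13 phosphate transport genes, 12 were at least 2-fold higher and none was lower (median log2 3.65), including PHT1;8 (4.87) and G3Pp1 (4.64), while PHO1, which loads phosphate into the xylem, was at -0.83. Of 16 phosphatase and nuclease genes, 14 were higher (median 2.84), with the acid phosphatase gene PAP17 at 4.50. Of 17 genes of membrane lipid remodelling, 13 were higher (median 2.93), with NPC4 at 5.13, MGD2 at 4.68 and SQD2, for sulfolipid synthesis, at 4.63. Each of these 3 medians lay above all 10000 random lists, but their size depended on the pseudocount. With a pseudocount of 208 they were 2.26, 2.13 and 2.04, PHT1;8 was at 3.81 and MGD2 at 3.96, and with 4.15 the phosphatase median was 4.42. It was 3.76 among genes with a mean of at least 208, and the transport median was over 1.5-fold smaller without a filter. Phosphate starvation signalling split: 5 of 15 genes were higher, 3 were lower, and the median of -0.16 lay at percentile 69.2 and became 0.09 with median-of-ratios scaling. The lower members were SPX4 (-1.18), NLA (-1.15) and PHO2 (-1.02), and none of these was 2-fold lower with median-of-ratios scaling. SPX4 was at -0.81 with a pseudocount of 208, and PHO2 was at -0.96 without low_Pi replicate 2 and -0.95 without plus_Pi replicate 2.

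**Figure D2:**
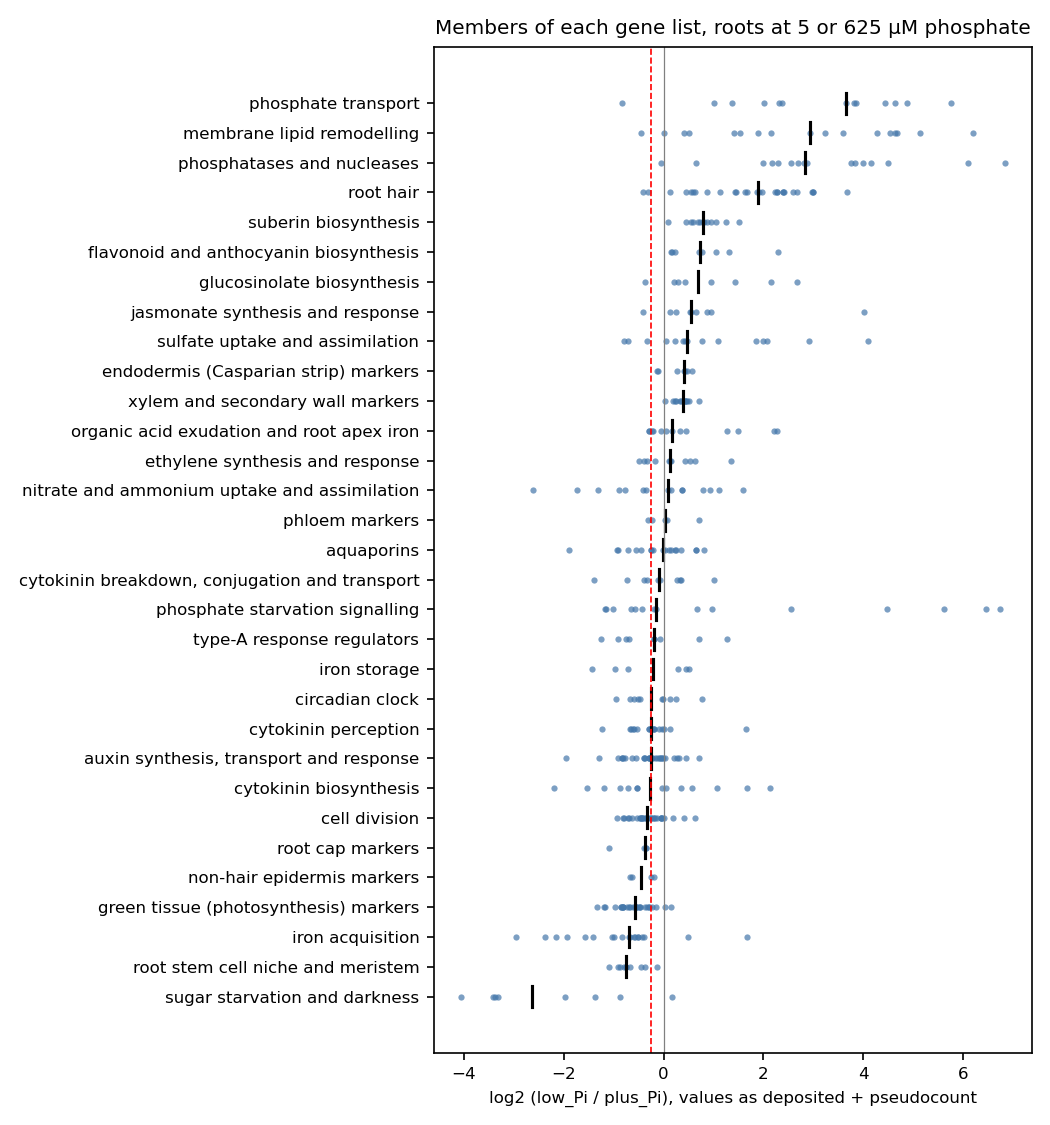
Log2 ratio of low_Pi to plus_Pi (horizontal) for the members of the 31 lists fixed by gene identifier (vertical), with 1 point per gene above the filter. Black bars are list medians, the grey line marks 0 and the dashed red line marks the median of all genes, -0.26. Phosphate transport has the highest median, 3.65, and sugar starvation and darkness the lowest, -2.64.

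Cytokinin biosynthesis genes included higher and lower members. Of 14 measured genes, 3 were at least 2-fold higher, 3 were lower and 8 lay in between, and the median of -0.28 was at percentile 49.7. Among the 9 genes with a mean of at least 208, the median was -0.53, at percentile 6.38 of random lists drawn from such genes. The tRNA isopentenyltransferase genes, which give rise to cis-zeatin, were both under 2-fold: IPT2 (AT2G27760) had 273 and 262 in low_Pi against 390 and 421 in plus_Pi (log2 -0.53), and IPT9 (AT5G20040) had 422 and 397 against 568 and 654 (log2 -0.53). Relative to the median gene, these differences were -0.28 and -0.27. Of the trans-zeatin hydroxylase genes, CYP735A2 (AT1G67110) was lower, at 474 against 1457 (log2 -1.54), and CYP735A1 (AT5G38450) had a log2 difference of -0.72. IPT3, an adenylate isopentenyltransferase gene, was lower at 52 against 389 (log2 -2.20), and IPT7 was lower at -1.19. The cytokinin-activating LOG2 (log2 2.13), LOG7 (1.68) and LOG5 (1.07) were higher. LOG2 was at 1.18 and IPT3 at -1.20 with a pseudocount of 208, which put LOG5 (0.47) and IPT7 (-0.50) under 2-fold.

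The downstream cytokinin lists each had 1 member at least 2-fold higher and 1 lower. Of 10 breakdown, conjugation and transport genes, 1 was higher (the glucosyltransferase gene UGT76C1, log2 1.02) and 1 lower (the cytokinin oxidase gene CKX4, -1.39), with the median of -0.08 at percentile 86.2 and at 0.07 with median-of-ratios scaling. UGT76C1 was under 2-fold with a pseudocount of 208 (0.79), without low_Pi replicate 1 (0.96) and without plus_Pi replicate 1 (0.97). Of 9 type-A response regulators, which are rapidly induced by cytokinin, ARR17 was higher (1.27) and ARR7 lower (-1.24), with the median of -0.20 at percentile 65.4 and at 0.06 with median-of-ratios scaling. This position depended on the filter: the 7 type-A genes with a mean of at least 208 were all below 0, with a median of -0.68 at percentile 0.61 of random lists drawn from such genes. ARR17 was at 0.54 and ARR7 at -0.92 with a pseudocount of 208, and ARR7 was also under 2-fold with median-of-ratios scaling. Of 17 perception and signalling genes, AHP1 was higher (1.65) and CRF1 lower (-1.23, from values of 12 and 84, and -0.41 with a pseudocount of 208), and the median of -0.25 was at percentile 49.4 and at 0.03 with median-of-ratios scaling.

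**Figure D3:**
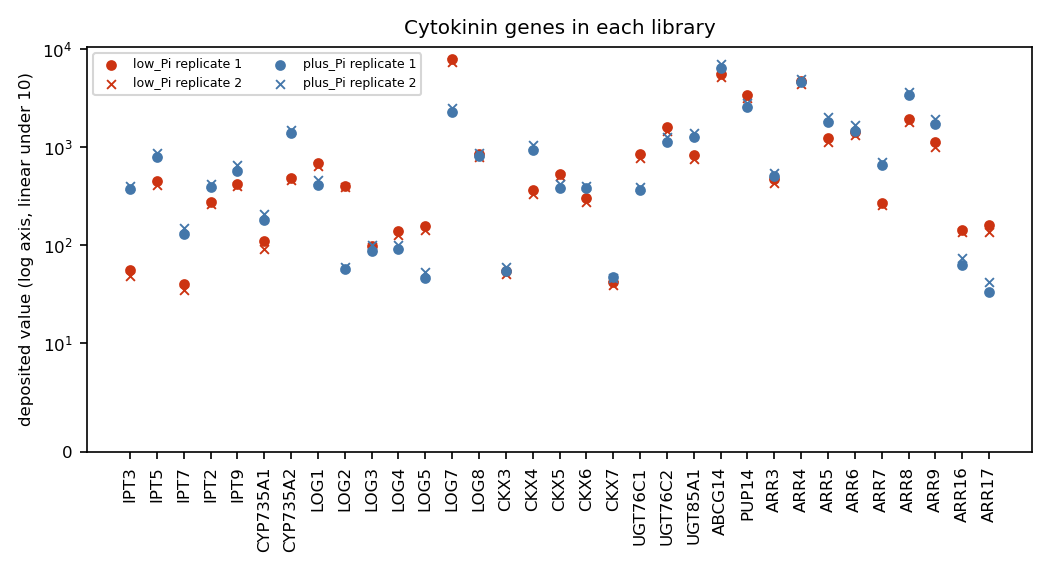
Deposited values (vertical, log axis, linear under 10) of cytokinin biosynthesis, breakdown, conjugation and transport genes and type-A response regulators above the filter (horizontal) in each of the 4 libraries. Columns of a group nearly coincide; IPT3 and CYP735A2 are lower and LOG2 and LOG7 higher in low_Pi.

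Root hair genes were higher as a group. Of 28 genes, 20 were at least 2-fold higher and none was 2-fold lower (median log2 1.90, above all 10000 random lists). XTH14, which modifies the cell wall, was at 2.99, RHS13 at 2.99 and XTH26 at 3.68, or 2.41 and 4.36 with pseudocounts of 208 and 4.15. Markers of non-hair epidermis had a median of -0.45 over 4 genes, at percentile 25.1. Suberin biosynthesis had 3 of 13 genes higher, CYP86B1 (5573 against 1944), GPAT7 (log2 1.25) and FAR5 (1.05), against 7 with median-of-ratios scaling and 2 without low_Pi replicate 1 or without plus_Pi replicate 1, where FAR5 was under 2-fold. The list had a median of 0.78, above all 10000 random lists. Endodermis markers had a median of 0.41 over 7 genes (percentile 99.6, CASP1 at 0.56), and xylem and secondary wall markers 0.38 over 12 genes (percentile 99.9), none of either 2-fold apart.

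Meristem genes had lower values. The median over 10 stem cell niche and meristem genes was -0.75, at percentile 0.08, and PLT3 was the 1 member at least 2-fold lower (-1.09), a call absent with median-of-ratios scaling, with a pseudocount of 208 and without low_Pi replicate 2. None of 31 cell division genes was 2-fold apart, and their median of -0.34 was at percentile 25.3. Root cap markers had a median of -0.37 over 4 genes (percentile 37.1), with SMB at -1.08, a call also absent with that scaling and that pseudocount. Phloem markers were at 0.03 over 5 genes (percentile 86.9), and at -0.03 without plus_Pi replicate 1.

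Iron acquisition genes were lower as a group. Of 19 genes, 7 were at least 2-fold lower and 1 was higher, and the median of -0.69 was at percentile 0.01. IRT1, the main root iron transporter gene, averaged 238 in low_Pi and 2105 in plus_Pi (log2 -2.94), CYP82C4 was at -2.38 and BHLH101 at -2.15, while IRT2 was higher at 1.67. BHLH101 was at -0.91 and CYP82C4 at -1.34 with a pseudocount of 208. Of 6 iron storage genes, VTL5 was lower (-1.44), against 2 genes without low_Pi replicate 1 or without plus_Pi replicate 1, and the median of -0.21 became 0.05 with median-of-ratios scaling. Organic acid and apex iron genes had a median of 0.16 over 13 genes (percentile 98.8). The 4 members at least 2-fold higher were PPCK1 (2.27), PPCK2 (2.22), PPC1 (1.49) and PPC3 (1.27), which encode phosphoenolpyruvate carboxylases and their kinases.

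SLAH1 and AT2G28780 were among the genes with the largest losses in low_Pi. SLAH1 (AT1G62280), a homologue of the anion channel gene SLAC1, averaged 18 in low_Pi and 2827 in plus_Pi (log2 -5.62). AT2G28780 was at -5.28, GSTF14 at -4.83, BT1 at -4.23 and the potassium channel gene SKOR at -4.23. Of 8 genes of sugar starvation and darkness, 6 were at least 2-fold lower (median -2.64, below all 10000 random lists), with DIN10 at -4.05, BT2 at -3.42 and BCAT2 at -3.37. Some of these losses depended on the pseudocount. With a pseudocount of 208, AT2G28780 was at -4.79 and thus below SLAH1 at -3.75, and AT2G28780, BT1, DIN10 and BT2 moved by under 1.5-fold in every setting tried. With the same pseudocount, GSTF14 was at -2.90, SKOR at -3.13 and BCAT2 at -1.77, and the list median was -1.60. The list median was -3.31 among genes with a mean of at least 208.

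Among other nutrients, sulfate uptake and assimilation had 6 of 15 genes higher and none 2-fold lower (median 0.48, above all 10000 random lists), with SULTR1;3 at 1230 against 33.5 (log2 2.58 and 5.10 with pseudocounts of 208 and 4.15), LSU2 at log2 2.92 and LSU1 at 2.07. Nitrate and ammonium genes split, with 2 of 15 higher and 3 lower, or 4 and 3 with median-of-ratios scaling (median 0.08, percentile 94.5, and -0.34 at percentile 11.0 among genes with a mean of at least 208). NRT1.5, a xylem-loading nitrate transporter gene, averaged 18921 against 116227 (log2 -2.62), NRT1.1 was at -1.73 and HHO2 at 1.58. Of 19 aquaporin genes, PIP2;3 was lower (-1.89) and is uncertain because of its close copy PIP2;2; with median-of-ratios scaling 1 gene was higher and 1 lower, and without low_Pi replicate 1 it was 2 lower. The median of -0.01 was at percentile 84.5 and at 0.26 with that scaling.

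Green tissue markers were lower in low_Pi. The median over 29 markers was -0.56, at percentile 0.13, with CA1 (-1.32), GAPB (-1.19) and PSAF (-1.16) at least 2-fold lower, of which 1 was so with median-of-ratios scaling. None was so with a pseudocount of 208 (CA1 -0.65, GAPB -0.58 and PSAF -0.95). Chloroplast-encoded genes made up 0.087% of the low_Pi replicate 1 total and 0.157% of the plus_Pi replicate 1 total. Because polyadenylated RNA was selected, the values cover only what that selection captured of the RNA of these genes. Of 43 such genes, 12 were at least 2-fold lower, 5 with median-of-ratios scaling, and 4 and 19 with pseudocounts of 208 and 4.15 (median -0.73, below all 10000 random lists).

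Ribosomal protein genes, matched by description and taking in organellar ones, had a median of -0.61 over 266 genes, below all 10000 random lists. Of these genes, 5 were 2-fold lower. With median-of-ratios scaling the median was -0.34 and 1 gene was 2-fold lower, and 0 and 11 were with pseudocounts of 208 and 4.15. Without low_Pi replicate 1 it was 8 genes, and without plus_Pi replicate 1 it was 10. Several named genes overlap another gene in the annotation, such as OCT1, PAP17, SKOR, DIN10 and NRT1.5. Whether strand separated the reads of such pairs is unknown, as the protocols do not mention it. The overlapping gene had a mean of 6053.5 for OCT1, 1613.5 for PAP17 and 2034.5 for NRT1.5. It was only 13.25 for SKOR and 5.75 for DIN10. For BCAT2, CA1 and BHLH101 the overlapping gene had the higher mean (1969.75 against 284.75, 237 against 137.25 and 168.25 against 112.25). For PLT3 it was nearly as high (810 against 917.5). The differences of these 4 genes are therefore less certain.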

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

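Fold sizes of 1.5 and 4, subtraction of the low_Pi share, linear means and a common total were chosen after seeing the data. Genes at least 2-fold higher in low_Pi (857) numbered 565 with a pseudocount of 208, 1643 at 1.5-fold and 272 at 4-fold, and 796 to 943 without 1 library. Genes 2-fold lower (838) numbered 1310 and 350 with pseudocounts of 4.15 and 208, 428 with median-of-ratios scaling, 440 with trimmed-mean scaling, 500 with quantile normalization, 3885 at 1.5-fold and 108 at 4-fold, and 695 to 1027 without 1 library. Scaling acts on the shared shift of -0.26. The planned limma test called 12951 genes (3211 higher, 9740 lower), 16987 with median-of-ratios scaling (8523 and 8464), 16944 with trimmed-mean scaling (8311 and 8633), 16971 with quantile normalization (7066 and 9905), 7208 with the replicate block, 1695 with a 2-fold requirement, and 7242 to 10967 without 1 library, where the lone library is assumed to vary like the other group. Replicate numbers are not stated to mark a shared batch, and deviations of same-numbered columns correlated at -0.11 across genes, which are not independent. Camera called 19 of 39 lists, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 21 with ranks, 19 with the replicate block and 19 without any 1 library. The estimated correlations ran from 0.51 for mitochondria-encoded genes to 0.99 for phloem markers, with 0.97 for aquaporins. Columns of a group differ in total and were not rescaled, so all genes shift together, and the estimate takes in that shift. The 0 calls therefore cannot tell whether members of a list vary together beyond it. With the preset correlation, camera did not call the glutathione S-transferase, histone, endodermis and ethylene lists, whose medians lay at percentiles of 98.0 or more. It called phosphate starvation signalling, at percentile 69.2. The median of the histone list (0.03) was -0.01 without low_Pi replicate 1, and ran from -0.024 to 0.089 over the omissions of 1 library. The median of all genes moved alike, to -0.32 without plus_Pi replicate 1 and -0.19 without plus_Pi replicate 2. The values were not rescaled and column totals differ, so each omission shifts all genes together. Calls that change when 1 library is omitted may reflect this shared shift. For example, without low_Pi replicate 1 the median of all genes moved from -0.26 to -0.31. FAR5 then moved from 1.05 to 0.99 and UGT76C1 from 1.02 to 0.96, which is about as much. Of 74 named genes at least 2-fold apart, 0 changed sign under 15 settings and 31 moved by over 1.5-fold. The filters and the replicate block leave the log2 difference of a gene unchanged, and scaling moves it by far less than 2-fold. The 0 sign changes therefore say little about how robust these genes are. The count model was not run because the values are called normalized and were not shown to be raw counts. Low values limit the precision of folds, as read depth is unknown.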

Other observations

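Jasmonate, glucosinolate and flavonoid genes had high medians in low_Pi. AOC1, for jasmonate synthesis, was the 1 of 9 jasmonate genes at least 2-fold higher, where median-of-ratios scaling gave 3, a pseudocount of 4.15 gave 4 and the omission of plus_Pi replicate 2 gave 2. It had 5 and 20 in the plus_Pi libraries, so its log2 difference of 4.01 was 2.23 with a pseudocount of 208 and 5.79 with 4.15. The list median of 0.55 was at percentile 99.99. Glucosinolate biosynthesis had 3 of 8 genes higher, BCAT4 (2.68), MAM1 (2.15) and MYB28 (1.44), with a median of 0.69 at percentile 99.95. Flavonoid and anthocyanin biosynthesis had 8 of 19 listed genes above the filter, with 3 higher, CHS (2.29), FLS1 (1.06) and CHI (177 against 47). Of these, FLS1 (0.62) and CHI (0.59) were under 2-fold with a pseudocount of 208. The list median of 0.74 was at percentile 99.95, and it was 0.23 without a filter on low values. In the ethylene list ACS7 was higher (1.35, and 0.72 with a pseudocount of 208), with a median of 0.13 over 11 genes at percentile 98.0. Auxin genes had a median of -0.25 over 31 genes at percentile 52.9, and 0.02 with median-of-ratios scaling, with GH3.2 (-1.95) and GH3.3 (108 against 326, and log2 -0.76 with a pseudocount of 208) lower. The 10 circadian clock genes had a median of -0.25 at percentile 55.0, none was 2-fold apart as deposited, and with median-of-ratios scaling the median was 0.02 and 1 was higher, while 1 was lower without low_Pi replicate 1 or without plus_Pi replicate 1.

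Peroxidases had 9 of 56 genes higher and 4 lower (median 0.10), and glutathione S-transferases 4 of 45 higher and 3 lower (median 0.24). With median-of-ratios scaling these were 10 higher and 1 lower, and 7 higher and 1 lower. With a pseudocount of 208 they were 6 and 1, and 2 and 1, and the transferases had 2 and 2 without low_Pi replicate 1 or without plus_Pi replicate 1. Both medians lay above all 10000 random lists. The histone family, which takes in histone methyltransferases, had a median of 0.03 over 45 genes at percentile 99.95. It had 3 genes higher and 1 lower, or 1 and 1 with a pseudocount of 208. Expansins (18 genes, median -0.16, percentile 81.7, and 0.11 with median-of-ratios scaling), heat shock proteins (50 genes, -0.28, percentile 21.3) and mitochondria-encoded genes (13 genes, -0.19, percentile 65.2) lay within the range of most random lists. AT2G34210, next to MIR399f in the TAIR10.1 annotation, averaged 2499 in low_Pi and 23.5 in plus_Pi (log2 5.32). It was singled out after its value was seen; of the 7 other neighbours of MIR399 genes, ZIP12 was at 2.37 and the others ran from -0.30 to 0.96, none of them 2-fold apart as deposited. AGP4 departed from the common ratio in both groups, with 1465 and 829 in low_Pi replicates 1 and 2 and 924 and 1553 in plus_Pi replicates 1 and 2.

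The tests of the 3 patterns below were chosen after the results they address had been seen. The first pattern is the closeness of the columns within a group. Independent reads deposited without rescaling would give a chi-square per gene of about 1 or more, and the low_Pi columns gave 0.278, which argues against that origin. Reads shared between columns, or deeper values scaled down before deposit, may both give values under 1, and the plus_Pi columns gave 0.296 after removal of the low_Pi share. These versions cannot be told apart because both lower the spread at every level. No biological explanation was tested.

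The second pattern is the excess of plus_Pi replicate 2 at genes high in low_Pi. All 36 genes at least 16-fold higher than in replicate 2 itself, a choice that works against an excess, had one at a low_Pi mean of at least 1000, with a median of 1.16% of the low_Pi level (quartiles 1.06% and 1.26%); mixing and a milder supply would both give this. The fitted share over 18491 genes was 1.13% (95% interval 1.08% to 1.17%). This interval covers only the resampling of genes, not variation between libraries. Medians over bands of fold size ran from 0.905% to 1.19%, outside the interval at both ends. Similar shares across bands are what low_Pi material or reads mixed into plus_Pi replicate 2 would give. A milder phosphate supply may instead have lowered the genes that are low in low_Pi, but the 108 genes at least 4-fold lower had a median replicate ratio of 1.09, close to the fitted scale of 1.09. A slight response of this kind cannot be told apart from mixing, since a small linear response would leave the same ratio.

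The third pattern is the median gene at -0.26. Unequal totals are not the whole source, because the median was -0.19 at a common column total. Genes at least 2-fold higher held 9.94% of the low_Pi total and 2.4% of the plus_Pi total, a direction set by how they were chosen. Leaving genes 2-fold apart either way out of the totals gave -0.13. A larger share taken by abundant genes may thus account for part of the shift. What remains cannot be told apart from a broad difference between the phosphate levels, because the authors' normalization is not given in the sources used here.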
